A study of Mus musculus with 6 samples.

How the data were processed

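The data are 6 arrays of total RNA from mouse heart ventricles, 3 of a sleep fragmented group and 3 of an undisturbed control group. The group and replicate number were taken from the end of each sample's title, because the titles of the controls carry the words for sleep fragmentation as well. Nothing states that the samples came from separate animals, so p-values measure the spread between these samples, which may be technical. Per the labels' protocols, RNA was purified on spin columns and labelled with Cy3 by a 1-colour amplification kit.

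The array scanner output was deposited as 1 file per sample. Per the file headers, intensity values (background-subtracted and spatially detrended spot signals, median spot signals and local background signals, on a linear scale) were made with Agilent Feature Extraction 11.0.1.1 for array design 026655. The submitters' processing notes name version 10.5.1.1, and the difference was not resolved. The deposited flags for spots well above background, saturated or outlying are other values, 0 or 1. A table of log2 values for the whole series was also deposited by the authors. Its processing is not given in the sources used here. Each of its columns had a median of 5.53, the 6 columns matched their own array's log2 signal with r of 0.998 or more and a slope between 0.93 and 1.05, and they carry no centring by gene. The table was used as an alternative only. Its counts lay close to those of quantile normalization (94 of 378 probes higher against 93 of 380, at an unadjusted limma p under 0.05 and at least 1.5-fold). It is therefore read as a near repeat of that alternative.

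From the processed intensity, log2 values were taken and each array's 75th percentile over all non-control probes was subtracted. Outlier spots (180 to 240 per array) and control spots were left out, and spots of 1 probe were averaged. No spot was saturated (0 on each array). Of 44397 spots per array, 39429 distinct non-control probes remained, and 25228 were kept because they were well above background on every array of at least 1 group. Probes were named by matching their unversioned RefSeq accessions to a gene table of assembly GRCm38.p6, since the files hold no column of gene names. The match named 27234 probes (69.1%) and left 12195 unnamed; 18545 kept probes had a name. The array was designed on another genome build, so no positions are given. For a gene with several probes the brightest kept probe stood for it. Of 3396 genes with more than 1 kept probe, 1346 had probes of opposite sign, 2 of them with both beyond 1.5-fold. No named gene was below background on every array of a group.

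Groups were compared with limma 3.58.1 (lmFit and eBayes with default settings, prior degrees of freedom 5.02) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all kept probes and a threshold of 0.05. A second count, at an unadjusted p under 0.05 and at least 1.5-fold, was fixed as a description. Fold changes are sleep fragmented over control, and errors are the moderated standard errors of single genes or, for lists, the standard error from the arrays' list means. The number of arrays limits the precision.

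Before the data were examined, 30 gene lists were fixed: 2 of the circadian clock, others of interferon, antigen presentation, pattern recognition, complement and cytokine genes, markers of neutrophils, macrophages, lymphocytes, erythroid cells and platelets, adipocytes, atrial tissue, fibroblasts and matrix, endothelium and smooth muscle, nerve, lung and thymus, and genes of contraction, hypertrophy, metabolism, stress and proliferation. Lists were tested by camera with a preset correlation of 0.01 between genes, with an estimated correlation beside it, and adjusted over the 30 lists. With the estimated correlation 0 lists passed. By fry, which tests whether the genes of a list move one way on balance, 0 lists passed. The smallest adjusted p by fry was 0.117, for the immediate-early genes, and it was 0.167 for the interferon-stimulated and clock negative limb lists. List means per array were compared by an exact permutation test, whose smallest p for 3 arrays against 3 is 0.1.

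The rule for named genes, fixed at the same time, took per direction up to 10 genes with the largest fold change among those past the adjusted threshold without overlap of the groups. Where fewer passed, it filled up to 10 with the smallest unadjusted p among genes at least 1.5-fold different without overlap, given as values that did not pass. It added up to 6 called members of each list, 4 members with the smallest p of the clock lists and the first 3 immune lists, and up to 2 of every other list; clone and predicted gene names were left out. Of the 80 genes it gave, the text names those that bear on a list or change sign. The result for 1 gene is not reported here.

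The fit was tested on simulated data: 25180 probes were drawn with the real means and spreads, and 50 probes each were changed by 1.5-, 2-, 3- or 5-fold. At an adjusted p of 0.05, 0%, 10%, 58% and 70% of them were recovered for this comparison, with 4 false calls, and 5.32% of the unchanged probes had an unadjusted p under 0.05. In a simulation of 30 lists, camera called the 1 changed list and 0 unchanged lists. Genes were drawn independently of one another there, so it cannot show how the preset correlation of 0.01 does with correlated genes. On the real arrays the estimated correlation was 0.52 within the interferon-stimulated list.

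Alternatives were normexp background correction (offset 50), quantile, median and detected-probe scaling, no filter or a stricter filter on dim probes, the replicate number as a block, eBayes with trend and robust, array weights, the authors' log2 table, the mean of a gene's probes, camera with an estimated correlation and leaving out each array. Leaving out an array reruns the filter on dim probes, which can change the members of a list, so each array was also left out with the members as on all 6 arrays. The normexp correction had been planned on mean spot signals; the files hold median spot signals, which were used in their place. The scan as a block was planned but could not be fitted, since each scan held 1 group.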

Results

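Total RNA from the cardiac ventricles of 21-week-old female mice of the C57BL/6N inbred strain was hybridised to 1-colour (Cy3) Agilent gene expression arrays, with 1 sample per array. The sleep of 1 group had been repeatedly interrupted for 5 weeks (sleep fragmentation, 3 arrays), and the control mice had been left undisturbed (3 arrays). The comparison asked which genes of the heart differ in expression after chronic sleep fragmentation. The series is presented as a study of innate immune and circadian genes, so gene lists on these themes are not independent of the study's own selection. Between 23341 (59.2%) and 28631 (72.6%) of 39429 probes were well above background on an array, with the lowest number on sleep fragmented replicate 1, whose 75th percentile of signal was 127 against 212 to 262 on the other arrays. After the filter on dim probes, 25228 probes and 14555 named genes were compared. All sleep fragmented arrays were read in 1 scan and all control arrays in another, so for every difference reported, scan and group cannot be told apart.

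Interferon-stimulated genes were lower in the sleep fragmented hearts, and genes of the clock's negative limb, erythroid genes and some cell cycle genes were higher. These lists passed by camera with the preset correlation, and 0 lists passed with an estimated one. With the preset correlation, every other split of the 6 arrays into 3 and 3 also gave between 5 and 20 lists. A camera call alone therefore does not mark a difference between the groups. Of the 10 genes with the smallest unadjusted p among those lower, 6 were interferon-stimulated genes of the fixed list (Usp18, Rtp4, Oasl1, Oas2, Oas1a and Ifit1) and 1 was the interferon-induced GTPase Gbp3. The others were Oas1f (3.50-fold lower), Phf11d (2.43-fold) and Phf11a (2.46-fold). Of the 10 among those higher, 4 were clock genes (Hlf, Per2, Dbp and Per1), 3 were globin genes (Hbb-bt, Hbb-bs and Hba-a1), 2 were cell cycle genes (Mki67 and Plk1) and 1 was the kinase gene Dclk3 (1.73-fold higher). The fixed lists together held 500 (3.44%) of the measured genes and 16 of these 20.

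**Figure D1:**
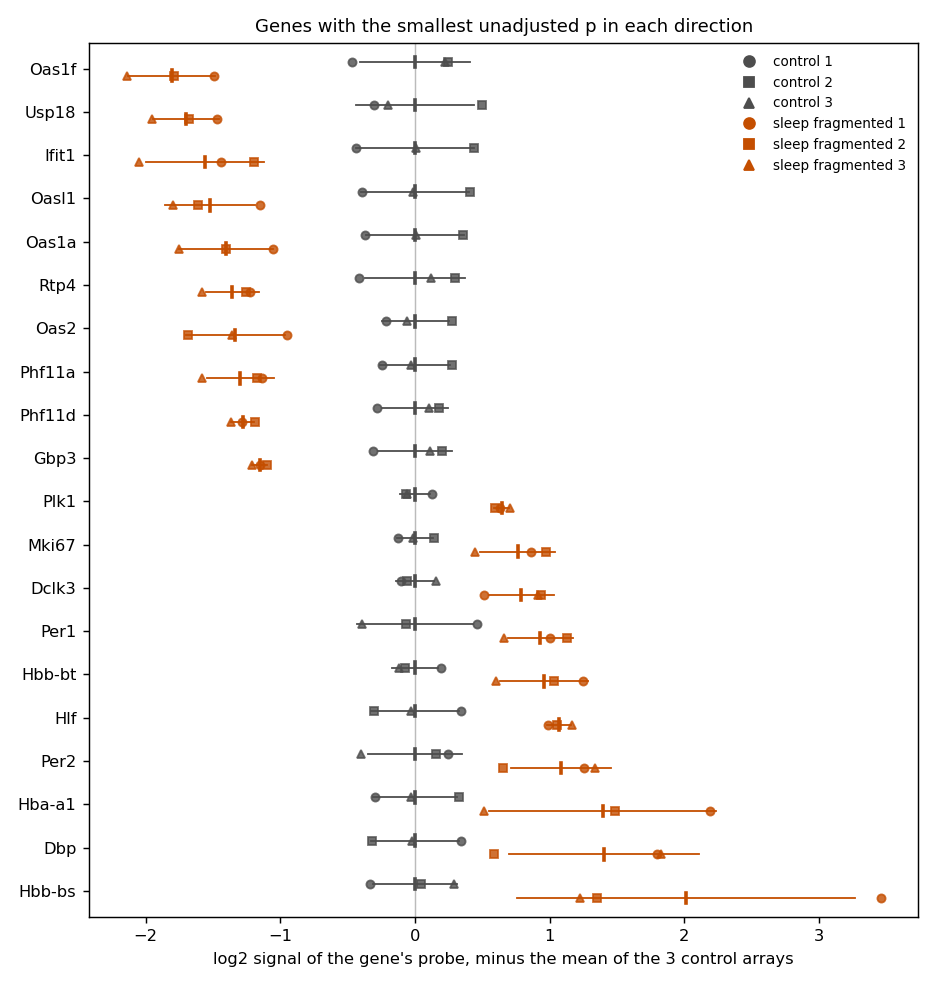
Log2 signal of each of the 20 genes with the smallest unadjusted p, 10 in each direction, minus the mean of the 3 control arrays (x axis, log2 units); each point is 1 array, vertical ticks are group means and horizontal lines are 1 SD to either side. For every gene shown the 3 sleep fragmented arrays lay beyond the 3 control arrays, which was part of the rule by which the genes were chosen.

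None of these genes passed the test over all probes. Of the 25228 probes, 0 had an adjusted p under 0.05 by limma, and the smallest adjusted p was 0.552. At an unadjusted p under 0.05 there were 735 probes, where chance alone gives 1261; the count was 2006 with the replicate block, 5997 with array weights and 2989 without control replicate 3. Of the 735 probes, 486 differed at least 1.5-fold, 317 higher and 169 lower in the sleep fragmented hearts. The share that was higher depended on the scaling: 65.2% with the 75th percentile, 24.5% with quantile normalization (93 of 380) and 13.8% with the median (92 of 667). The median log2 fold change of all kept probes moved with it, from 0.08 to 0.0023 and -0.13. Without control replicate 3 the count of 486 became 2705, and without sleep fragmented replicate 2 it became 1093. With array weights in the fit, 53 probes passed the adjusted threshold, 17 higher and 36 lower, with the replicate block 4 and with normexp background correction 3. The arrays of the groups did not overlap for 1108 genes (7.63%), where chance gives 10%.

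**Figure D2:**
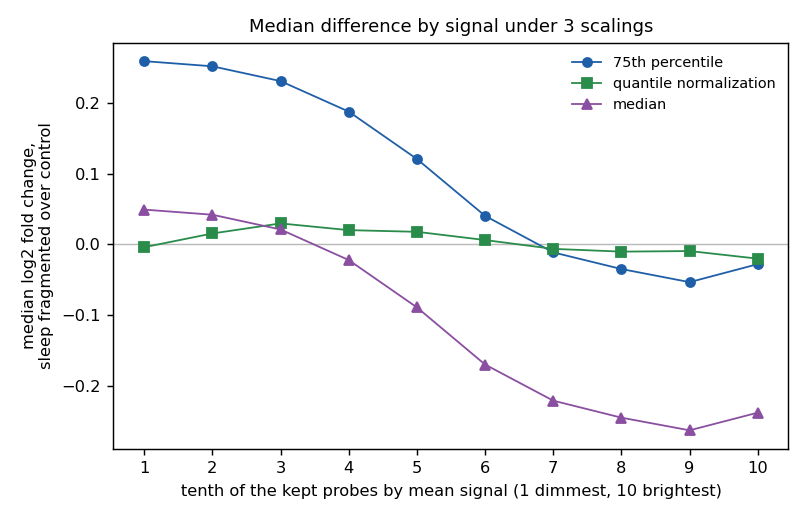
Median log2 fold change of sleep fragmented over control (y axis) in 10 equal bins of the kept probes by mean signal (x axis), under 3 scalings. With the 75th percentile the dimmest bin lay at 0.26 and the brightest at -0.028, and with quantile normalization all bins lay between -0.020 and 0.029.

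Interferon-stimulated genes, which encode antiviral effectors and the signalling proteins that induce them, were lower as a group. Over the 29 measured members the mean log2 fold change was -0.86 ± 0.25 (SE, n = 3 arrays per group), and 25 members had a negative value. Adjusted over the list alone, 20 of the 29 fell, by 1.55- to 3.25-fold, 0 rose and 9 did not pass, and over all probes 0 passed. In 18 of these 20 every sleep fragmented array lay below every control array. Usp18, the protease that removes the ubiquitin-like modifier Isg15 from proteins, was 3.25-fold lower (log2 fold change -1.70 ± 0.25). Ifit1, which binds viral RNA, was 2.95-fold lower (-1.56 ± 0.29). The oligoadenylate synthetase family members Oasl1 (-1.52 ± 0.26), Oas1a (-1.40 ± 0.25, its other kept probe at -0.63) and Oas2 (-1.33 ± 0.24) and the chaperone gene Rtp4 (-1.36 ± 0.23) also fell. So did Irf9 (-1.08 ± 0.21) and Stat2 (-0.96 ± 0.19), subunits of the transcription factor that type I interferon activates; these genes were chosen after their values were seen. Irf7 (0.02 ± 0.28) and Rsad2 (0.51 ± 0.36), also in the list and also chosen after their values were seen, did not pass. Where a member had more than 1 kept probe, the probe not used was weaker for some, such as Isg15 (-0.04 against -1.26). For others it was stronger, such as Xaf1 (-1.40 against -0.92).

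The list passed by camera (adjusted p = 4.24e-33) but not when the correlation between its genes was estimated from these arrays (adjusted p = 0.436 with an estimated correlation). All 3 sleep fragmented arrays had lower list means than all 3 controls, which gives an exact permutation p of 0.1, two-sided, the smallest that 3 arrays against 3 allow. Array positions here are numbers given to the barcodes recorded with the arrays, not taken from recorded places on a slide. Each position held 1 array of each group. Within them the difference was -0.25, -1.14 and -1.18. Whether a shared barcode means a shared slide was not resolved.

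**Figure D3:**
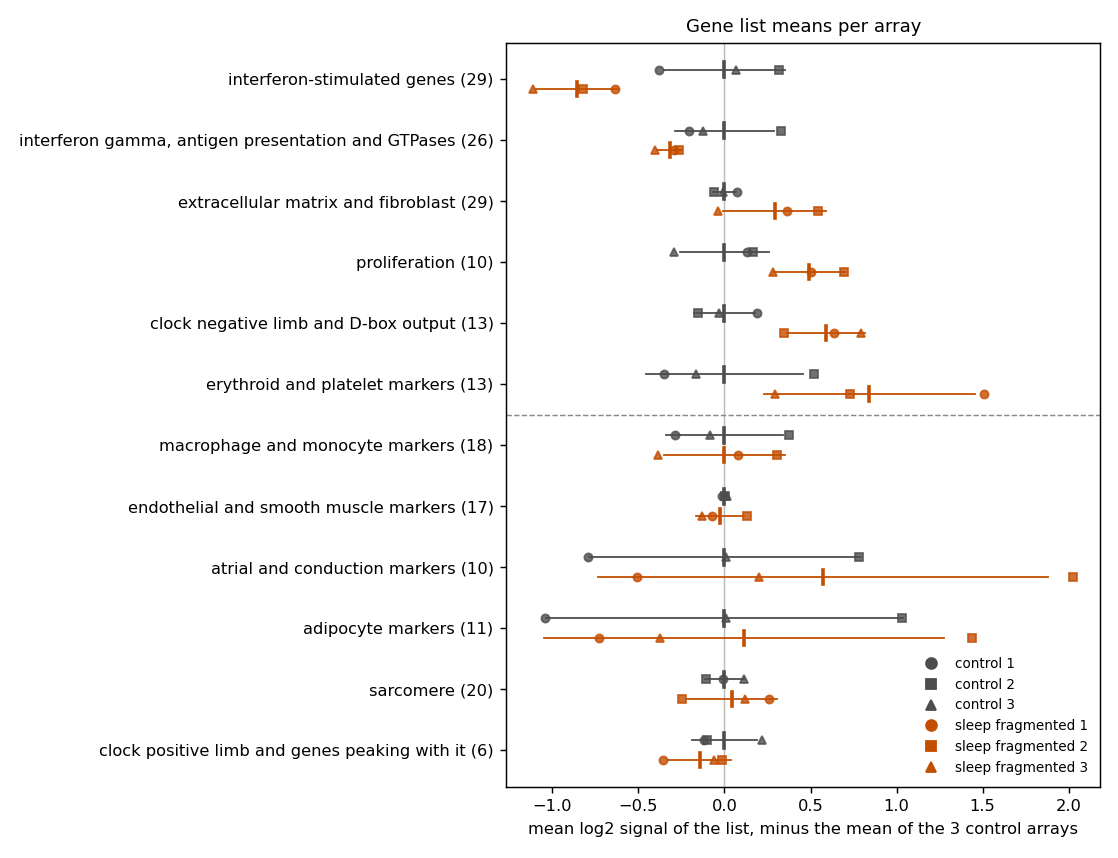
Mean log2 signal of the measured members of each list, minus the mean of the 3 control arrays (x axis, log2 units), with the number of members in brackets; each point is 1 array, vertical ticks are group means and horizontal lines are 1 SD to either side. The 6 lists above the dashed line passed by camera, and the interferon-stimulated list lay between -1.11 and -0.64 on the sleep fragmented arrays and between -0.38 and 0.31 on the controls.

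Genes induced by interferon gamma, of antigen presentation and of the interferon-induced GTPase families were lower by less. The mean log2 fold change over 26 members was -0.32 ± 0.17 (SE, n = 3 per group), with 21 negative values. Adjusted over the list alone 1 of the 26 fell, Gbp3 (2.23-fold lower, -1.15 ± 0.20), and 25 did not pass, among them Gbp6 (-1.05 ± 0.34), Irgm1 (-0.76 ± 0.22) and Irgm2 (-0.59 ± 0.21). The other kept probes of Gbp6 and Irgm1 stood at -0.30 and -0.56. Under the alternatives between 1 and 5 members fell, 5 of them with normexp and 5 with array weights, where 1 rose. The list passed by camera (adjusted p = 4.25e-08) and not with the estimated value (adjusted p = 0.436 with an estimated correlation), and its exact permutation p was 0.1. Much of the difference lay on control replicate 2, whose list mean was 0.33 against -0.20 and -0.12 on the other controls, and without it the mean was -0.15 (adjusted p = 0.0137). On that array the antigen presentation genes H2-Eb1 (2.78), H2-Ab1 (2.91) and Cd74 (0.71) were the highest of the 6 arrays, on the log2 scale relative to the 75th percentile, and so were the B cell genes Jchain (2.21) and Cd79b (0.99); these genes were chosen after their values were seen. Within array positions the differences were -0.09, -0.59 and -0.28.

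The other immune lists did not pass. The list means were 0.05 ± 0.10 (adjusted p = 0.868) for pattern recognition and inflammasome genes, 0.14 ± 0.46 (0.778) for complement and -0.01 ± 0.20 (0.314) for cytokines, chemokines and NF-kappaB targets. Ccl2, a monocyte chemoattractant, had a log2 fold change of -0.50 ± 0.21 and Tnfaip3, an inhibitor of NF-kappaB signalling, one of -0.51 ± 0.30. Marker lists of the cells that carry such genes had means of -0.15 ± 0.27 for neutrophils (adjusted p = 0.778), -0.0020 ± 0.28 for macrophages and monocytes (0.828) and -0.09 ± 0.36 for lymphocytes (0.909). Single arrays decided several of these values: without control replicate 2 the macrophage mean was 0.19, the lymphocyte mean 0.23 and the complement mean 0.43, all past the threshold and with the members unchanged.

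Genes of the clock's negative limb and of D-box output were higher as a list in the sleep fragmented hearts. The list also holds Wee1, Usp2 and Tsc22d3, the last of which is in the glucocorticoid-responsive list too. All 13 measured members had a positive log2 fold change, with a mean of 0.59 ± 0.17 (SE, n = 3 per group). Adjusted over the list alone 4 of the 13 rose, 0 fell and 9 did not pass, and over all probes 0 passed. The D-box transcription factor genes Dbp and Hlf were 2.64-fold (log2 fold change 1.40 ± 0.34) and 2.10-fold (1.07 ± 0.21) higher, and the clock repressor genes Per2 and Per1 were 2.12-fold (1.08 ± 0.26) and 1.91-fold (0.93 ± 0.25) higher. Per2 was kept through the sleep fragmented arrays, being well above background on 2 of the 3 controls, so its fold is uncertain, and with only probes above background on all arrays it left the list and 3 of 12 members rose. For each of the 4 every sleep fragmented array lay above every control array. Members that did not pass, chosen after their values were seen, included Nr1d1 (0.23 ± 0.25) and Cry2 (0.20 ± 0.20).

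This list passed by camera (adjusted p = 4.25e-08), not with the estimated value (adjusted p = 0.436 with an estimated correlation), and its exact permutation p was 0.1. The differences within array positions were 0.45, 0.50 and 0.82. With single arrays left out and the same 13 members the mean lay between 0.49 and 0.72, and without sleep fragmented replicate 1 only 1 member rose. Genes of the positive limb, which peak in the opposite phase, had a list mean of -0.14 ± 0.15 over 6 members and did not pass (adjusted p = 0.228). Arntl, the partner of Clock in the activating complex, had a log2 fold change of -0.65 ± 0.33, Nfil3 of -0.50 ± 0.28, Clock of -0.30 ± 0.20 and Arntl2 of 0.44 ± 0.29, and none of these passed over the list alone. With array weights the log2 fold change of Nfil3 was 0.0024. The clock time at which hearts were collected is not given in the sources used here.

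Erythroid genes were higher in the sleep fragmented hearts, most on replicate 1. Over the 13 measured erythroid and platelet markers the mean log2 fold change was 0.84 ± 0.44 (SE, n = 3 per group), and adjusted over the list alone 6 rose, 0 fell and 7 did not pass. Alas2, which catalyses the first step of heme synthesis in erythroid cells, was 4.06-fold higher (2.02 ± 0.59). The globin genes Hbb-bs (2.01 ± 0.52), Hba-a1 (1.40 ± 0.38), Hbb-b2 (2.14-fold higher) and Hbb-bt (0.96 ± 0.22) rose as well. Globin genes of the same chain, alpha or beta, are near-identical copies whose probes may bind one another's transcripts, so how the signal divides among them is uncertain. The platelet genes of the list, chosen here after their values were seen, did not pass, with -0.51 ± 0.85 for Ppbp, -0.20 ± 0.37 for Pf4, -0.06 ± 0.67 for Gp9 and 0.35 ± 0.24 for Itga2b. Ppbp stood at 3.42 on control replicate 2 and at -0.24 and 0.03 on the other controls.

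The erythroid and platelet list passed by camera (adjusted p = 4.20e-06) and not with the estimated value (adjusted p = 0.436 with an estimated correlation). Its exact permutation p was 0.2: relative to the control mean the sleep fragmented arrays lay at 1.51, 0.73 and 0.29 and control replicate 2 at 0.52. Without sleep fragmented replicate 1 the mean was 0.51 and 1 member rose, and without control replicate 1 the mean was 0.67 and 1 member rose. With a trended and robust prior 2 members rose. Within array positions the differences were 1.86, 0.21 and 0.46.

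Extracellular matrix and fibroblast genes had a mean log2 fold change of 0.29 ± 0.18 (SE, n = 3 per group), with 25 of 29 members positive, and 0 of the 29 passed over the list alone. The largest by rank of p were Lox, a collagen crosslinking enzyme (0.61 ± 0.23), and the collagen gene Col1a2 (0.58 ± 0.28), which did not pass. The list passed by camera (adjusted p = 0.00134) and not with the estimated value (adjusted p = 0.746 with an estimated correlation), and its exact permutation p was 0.3. The call was lost without control replicate 3 (adjusted p = 0.180), without sleep fragmented replicate 2 (mean 0.16, adjusted p = 0.514) and with array weights (mean 0.028, adjusted p = 0.804), and without sleep fragmented replicate 3 the mean was 0.46. Within array positions the differences were 0.29, 0.61 and -0.03. Relative to the control mean, the array highest in this list, sleep fragmented replicate 2 (0.55), was also the array highest in atrial (2.03), adipocyte (1.44) and nerve markers (0.85).

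Cell cycle genes had a mean log2 fold change of 0.49 ± 0.19 (SE, n = 3 per group) over 10 measured members, 7 of them positive. Adjusted over the list alone 3 rose: Mki67, a nuclear protein of dividing cells (0.76 ± 0.20), the mitotic kinase gene Plk1 (0.64 ± 0.17) and the cyclin gene Ccna2 (0.97 ± 0.28). Pcna, the sliding clamp of DNA replication, had a value of -0.02 ± 0.19; it was chosen after its value was seen. The list passed by camera (adjusted p = 9.73e-04) and not with the estimated value (adjusted p = 0.436 with an estimated correlation), and its exact permutation p was 0.1. The mean log2 fold change of the list proliferation was 0.35 without control replicate 3 (adjusted p = 0.215) and 0.39 without sleep fragmented replicate 2 (adjusted p = 0.0588), with the same 10 members, and neither passed. Nor did it pass with array weights (0.27) or with only probes above background on all arrays (0.28, 7 members). The 3 single calls were less stable: 0 members rose with quantile normalization, median scaling, normexp, the authors' table or no filter on dim probes, and 0 when control replicate 1 or 3 or sleep fragmented replicate 1 or 2 was left out, but 6 with the replicate block, without control replicate 2 or without sleep fragmented replicate 3, and 5 with array weights. Of the 21 fixed members 10 were kept, and Plk1 and Ccna2 were kept through the sleep fragmented arrays, being well above background on 2 of the 3 controls. Plk1 and Ccna2 had control means of -2.88 and -2.83 on the log2 scale relative to the array's 75th percentile, among the dim probes whose median differed by up to 0.26 between the groups. Within array positions the list differed by 0.37, 0.53 and 0.58.

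Genes of contraction and its control did not pass as lists. The means were 0.04 ± 0.16 for sarcomere genes (adjusted p = 0.868), 0.05 ± 0.15 for calcium handling and excitation (0.868), -0.03 ± 0.12 for beta-adrenergic signalling (0.254) and -0.04 ± 0.29 for the fetal and hypertrophy program (0.265). Gja1, the main gap junction protein of ventricular muscle, had a log2 fold change of -0.42 ± 0.18, Rcan1, a calcineurin regulator, of -0.39 ± 0.19 and Tcap, which caps titin at the Z-disc, of 0.31 ± 0.22. Metabolic lists had means of -0.06 ± 0.12 for fatty acid oxidation and PPAR-alpha targets (adjusted p = 0.155), 0.01 ± 0.11 for glycolysis (0.658) and -0.04 ± 0.18 for oxidative phosphorylation (0.130). The mitochondrial carrier gene Ucp2 had a log2 fold change of 0.75 ± 0.24 and Angptl4, an inhibitor of lipoprotein lipase, one of -0.89 ± 0.46. The mean log2 fold change of the list oxidative phosphorylation, nuclear genes, passed with quantile normalization (-0.11, adjusted p = 0.00831) and median scaling (-0.25, adjusted p = 0.0182), and without control replicate 2 or sleep fragmented replicate 1 (means of -0.12 and -0.18).

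Stress and cell type lists did not pass either. Means were 0.17 ± 0.07 for glucocorticoid-responsive genes (adjusted p = 0.0881), 0.20 ± 0.04 for immediate-early genes (0.130), 0.07 ± 0.09 for heat shock genes (0.868), -0.02 ± 0.06 for the unfolded protein response (0.254) and -0.04 ± 0.12 for oxidative stress and NRF2 targets (0.184). The exact permutation p of the immediate-early list was 0.1, as small as for the interferon-stimulated list. For marker lists they were -0.026 ± 0.080 for endothelial and smooth muscle cells (0.398), 0.29 ± 0.29 for nerve and Schwann cells (0.254), 0.11 ± 0.90 for adipocytes (0.778), 0.57 ± 0.88 for atrial and conduction tissue (0.0743) and 0.22 ± 0.34 for lung and thymus (0.552). With quantile normalization the mean log2 fold change of the list glucocorticoid-responsive genes was 0.16 (adjusted p = 0.00420) and the mean log2 fold change of the list atrial and conduction markers 0.49 (adjusted p = 0.0372), both past the threshold. The atrial list also passed without control replicate 2 (0.97), although its spread between arrays was wider than the difference. For 10 of the 24 lists that did not pass, the mean, the median and the direction of the test differed in sign.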

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

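Of 25 alternatives run, 7 were chosen after seeing the data: each of the 6 arrays left out with the list members unchanged, and 2 arrays against 2, without the arrays at the ends of the first principal component (sleep fragmented replicate 1 and control replicate 2). The scan as a block was not run, because each scan held 1 group. The interferon-stimulated, interferon gamma, clock negative limb and erythroid lists kept their direction and their call under all alternatives except camera with an estimated correlation, which leaves the means at -0.86, -0.32, 0.59 and 0.84 and calls 0 lists (adjusted p = 0.436 for each). It also ended the call of the matrix (0.29, adjusted p = 0.746) and proliferation lists (0.49, adjusted p = 0.436). The matrix call was lost with array weights (0.028), and the proliferation call with array weights (0.27) and with only probes above background on all arrays (0.28), which leaves 7 members. Unless stated, the cause was not tested.

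The number of probes past the adjusted threshold, 0, became 3 with normexp, 4 with the replicate block and 53 with array weights, and stayed at 0 to 0 when arrays were left out in turn. The 486 probes at an unadjusted p under 0.05 and at least 1.5-fold became 179 with normexp, 1413 without a filter on dim probes, which adds dim probes, 845 with the replicate block and 1266 with array weights; with single arrays left out they ranged from 408 to 2705. The 6 lists became 11 without the filter, 11 with 2 arrays against 2 and 0 with an estimated correlation, and 4 (without control replicate 3) to 14 (without control replicate 2) with single arrays left out, 12 without control replicate 1 and 10 without sleep fragmented replicate 3. With the members unchanged the counts were 10 without control replicate 1, 14 without control replicate 2 and 10 without sleep fragmented replicate 3. With single arrays left out, which reruns the filter and can change the members, list means ranged from 0.49 to 0.96 (clock), -1.05 to -0.70 (interferon-stimulated), -0.44 to -0.15 (interferon gamma), 0.51 to 1.12 (erythroid), 0.16 to 0.46 (matrix) and 0.27 to 0.72 (proliferation). The 0.96 includes Ciart (4.09), a clock gene that enters the list without sleep fragmented replicate 2; with the same 13 members the highest mean was 0.72. With the same 10 members proliferation ranged from 0.35 to 0.60, its call lost without control replicate 3 (0.35) and sleep fragmented replicate 2 (0.39), and the matrix call was lost on the same arrays (0.29 and 0.16).

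Whether the replicate numbers pair the samples stays open. Deviations from the group means correlated at 0.06, 0.55 and 0.21 for the same-numbered arrays. Of the 6 arrays, 2 correlated best with their own number, and 3 with quantile normalization. Deviations of so few arrays cancel within each group, so these values cannot settle it. The replicate block, which is also the array position, moved no list call of the 6.

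List values that reversed and passed were the macrophage (0.19) and lymphocyte (0.23) means without control replicate 2 (each with the members unchanged, too) and the adipocyte mean without control replicate 1 (-0.62). With the same 11 members the adipocyte mean was -0.41, still reversed, and did not pass, so the call but not the sign rests on members that the filter admits, as does part of the macrophage mean without control replicate 1 (-0.23, and -0.15 with the same 18 members). With single arrays left out these ranged from -0.23 to 0.19, -0.28 to 0.23 and -0.62 to 0.63. Of the 80 genes, 64 kept their sign throughout, and 19 of 1431 values reversed. With 2 arrays against 2 these were Ager (-0.013), C6 (-0.19) and Fabp4 (-0.13), with a log2 fold change of C7 of -0.067, a log2 fold change of Arntl2 of -0.0015, a log2 fold change of Ticam1 of -0.0075 and a log2 fold change of Tnnt2 of -0.0057. With array weights they were Col1a2 (-0.0046), Fabp4 (-0.032), Nr4a1 (-0.14), Pmp22 (-0.0065) and Txnip (0.030), with a log2 fold change of Nfil3 of 0.0024 and a log2 fold change of Pfkfb2 of 0.0063. The others were Fabp4 (-0.018) and Gpi1 (-0.023) with median scaling and Fcgr1 with normexp (0.031). With single arrays left out Fabp4 ranged from -0.082 (without sleep fragmented replicate 1) to 0.35 and the log2 fold change of Cgas from -0.085 (without control replicate 3) to 0.44. Dim probes, near the background on sleep fragmented replicate 1, limit what the arrays can resolve.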

Other observations

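Atrial and adipocyte transcripts differed between arrays of the same group by far more than between the groups. On the log2 scale relative to each array's 75th percentile, the atrial light chain gene Myl7 stood at 2.51 on control replicate 2, 3.56 on sleep fragmented replicate 2 and -2.81 on sleep fragmented replicate 1. The adipokine gene Adipoq stood at 1.97, 2.87 and -2.65 on the same arrays. The list means relative to the control mean ran from -0.79 (control replicate 1) to 2.03 (sleep fragmented replicate 2) for atrial markers and from -1.04 to 1.44 on the same arrays for adipocyte markers. These genes were chosen after their values were seen.

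Tests of macrophage, endothelial, Arntl, glucocorticoid and blood cell values were chosen only after the results they bear on were seen, and so was the rule that their bounds must also hold with each array left out, against the pattern in the same fit. An effect of scan applies to every pattern here and cannot be told apart from sleep fragmentation, since 0 scans held arrays of both groups. Sleep fragmentation itself stays open for each pattern and was not tested apart from it.

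Interferon-stimulated genes were lower, by -0.86 on average. A difference left by the scaling would shrink under quantile normalization, where the mean was -0.89 ± 0.25, and a single array does not account for it, since the smallest mean with an array left out was -0.70 ± 0.26 (without control replicate 2). Fewer endothelial and smooth muscle cells would lower their own markers, whose mean of -0.026 ± 0.080 lay above -0.43, the midpoint between 0 and the interferon-stimulated mean, by more than its error, as it did with each array left out. Fewer macrophages as the whole cause would lower their markers by about -0.86. The 18 members had a median of 0.049 (SD 0.34), which lay above the interferon-stimulated mean by more than the SD, as it did with each array left out. This SD is the spread of genes on the same arrays, not an error of the group difference. With the error from the arrays, the macrophage list mean of -0.0020 ± 0.28 lay above the midpoint by more than its error. In 2 fits it did not: without control replicate 3 (-0.045 ± 0.39, midpoint -0.41) and without sleep fragmented replicate 2 (-0.16 ± 0.30, midpoint -0.44). A part of macrophages in the difference therefore stays open. A lower interferon tone after sleep fragmentation may be one reading, with the scan open.

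Clock negative limb and D-box genes were higher, by 0.59 on average. Scaling and single arrays leave the difference in place, with a mean of 0.56 ± 0.14 under quantile normalization and a smallest mean of 0.49 ± 0.18 with an array left out (without sleep fragmented replicate 3). A rise in glucocorticoid signalling would raise other responsive genes, whose mean without Per1 and Tsc22d3 was 0.12 ± 0.07, below 0.30, the midpoint between 0 and the clock mean, by more than its error on all arrays and with each left out. That bears on a rise as large as the midpoint only, and 3 arrays per group are too few to exclude one. A smaller rise stays open too, and with it a part in the difference. On all arrays the mean lay above 0 by more than its error, and 18 of the 21 members of the full list were higher. Collection of the 2 groups at different clock times could give the same pattern and stays open: Arntl, which peaks in the opposite phase, had a log2 fold change of -0.65 ± 0.33, an error that reaches past -0.5, the value set as needed. A shift of the heart's clock by sleep fragmentation may look alike, and collection times would be needed to separate them.

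Erythroid genes, the list without its 4 platelet genes (a subset chosen after seeing the data), were higher by 1.26 ± 0.54 on average over 9 genes. Quantile normalization left 1.22 ± 0.46, but without sleep fragmented replicate 1 the mean was 0.75 ± 0.26, an error that reaches past 0.63, so how much of the difference rests on that array stays open. More whole blood left in the ventricle would bring abundant neutrophil and platelet transcripts, but S100a8, S100a9, Ppbp and Pf4 had a mean of -0.78 ± 0.84, which rests on control replicate 2 but without it, at 0.013 ± 0.49, still lay below 0.63 by more than its error. The other neutrophil markers went both ways, from -0.56 ± 0.27 (Chil3) to 0.57 ± 0.27 (Mmp8, a dim probe). The blood genes were few, chosen after the result and spread widely between arrays, so they cannot decide the question. Whole blood stays open as a whole or a partial cause. A higher share of young red blood cells may be one reading, which was not tested.

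The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 0 probes past the adjusted threshold, as did all 10, with a highest other of 0. It gave 486 probes at an unadjusted p under 0.05 and at least 1.5-fold, with a highest other of 3739 (6 splits gave as many, the real one included), and 6 lists, with a highest other of 20 (8 splits). The lowest other number of lists was 5, so camera with the preset correlation called lists in every split. The split with 3739 probes set control replicates 1 and 2 and sleep fragmented replicate 2 against the rest. These 3 arrays had the highest ratios of the 75th percentile to the median of signal, 4.83, 5.77 and 4.64 against 3.75 to 4.14. With quantile normalization the same split gave 1425 probes, so its count depended on the scaling.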
